A study of Mus musculus with 7 samples.

How the data were processed

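Total RNA of colon lamina propria macrophages was hybridised to Affymetrix Mouse Gene 2.0 ST arrays, 1 array for each of 3 LysM+/+ and 4 LysM+/cre samples, with no technical replicates per the labels. RNA was taken up in Trizol and purified on micro columns, and amplified, fragmented and biotin-labelled, per the labels' protocols. The deposited values are log2 intensities per probe set, already on a common scale across arrays. They were made with Affymetrix Expression Console, per the series' design text, and Transcriptome Analysis Console is also named in the submitters' processing notes. The versions, the summarisation algorithm and the background correction are not given in the sources used here. Nearly equal quantiles on the 7 arrays show that the values were normalized between arrays before deposit, which would hide a shift shared by all genes. Log2 differences on such arrays are often compressed for dim and very bright probe sets.

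Probe sets were named from the platform annotation supplied with the values. Of 41345 probe sets, 23521 had exactly 1 gene symbol, 1814 had several and were not named, and 16010 had none listed. Symbols were checked through Entrez identifiers against a RefSeq gene table of assembly GRCm38.p6, used only for names and for which genes neighbour each other. All but 193 identifiers matched, and 0 symbols changed. For the 1082 genes with several probe sets the one with the highest mean over all arrays was taken, which left 22180 genes. In 3 of these genes probe sets disagreed in direction at an unadjusted p under 0.05. No filter on dim probe sets was applied.

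Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), as LysM+/cre minus LysM+/+, two-sided, with no covariate and with Benjamini-Hochberg adjustment over all genes at 0.05. Genes past 1.5-fold at an unadjusted p under 0.05 were counted beside it. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over all 28 lists, of which 520 of 575 listed genes were measured. Estimated correlations and fry were alternatives. Each list also gave 1 score per array, the mean deviation of its members from their means over the 7 arrays, compared by an exact permutation test over all 35 splits of the arrays. Differences are log2 values, with the SE or SD named where printed.

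The tests, lists and the rule for naming genes were set before the data were examined. Rictor, Lyz2 and Spp1 were always to be named, and Spp1 was not analysed here. Then came the 12 genes per direction with the largest difference past the adjusted threshold. Where fewer passed, the places went to genes of smallest unadjusted p among those at least 1.5-fold different whose higher group lay above the median gene. From each list up to 4 members past an adjusted p of 0.05, over all genes or over the list alone, were named, or otherwise up to 3 of smallest p. Predicted genes, microRNAs and receptor or immunoglobulin segments were counted but not named. After the data were seen, the 15 largest differences per direction past the loose threshold were added. So were lists of HIF targets and of myeloid receptors and adaptors, from which members at an unadjusted p under 0.05 are named.

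The code was tested on 20 simulated data sets of 22180 genes with 200 changed genes, made for this comparison of 3 and 4 arrays. It recovered 73.4% of genes changed 2-fold and 95% of those changed 4-fold, and 5.42% of calls were false. A list shifted by 0.25 was called in all 20 simulations with the preset correlation and in 19 with an estimated one. The genes of that list varied independently, whereas the estimated correlation of the real oxidative phosphorylation list was 0.43. A shifted list of correlated genes was not simulated, so how often an estimated correlation would miss such a shift is not known. A list with no shift whose genes shared a correlation of 0.4 was called in 7 of 20 with the preset correlation and in 0 of 20 with an estimated one. Alternatives were other scalings, a filter on dim probe sets, other ways to treat probe sets, other variance models, array weights, cell type scores as covariates, the replicate number as a block, and leaving out each array. Figures were drawn with matplotlib 3.10.9.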

Results

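Gene expression was measured in macrophages sorted from the lamina propria of the inflamed mouse colon, on 7 Affymetrix Mouse Gene 2.0 ST arrays with 1 array per sorted sample. Colitis had been induced with dextran sulphate sodium (DSS), a polysaccharide that injures the colon epithelium, given at 5% for 5 days and followed by 3 days of plain water. The sorted cells carried CD45, CD11b, CD64 and MHC class II and lacked Ly6C. All mice carried floxed alleles of Rictor, which encodes a subunit of the kinase complex mTORC2. In 4 samples the mice also carried 1 copy of cre recombinase in the LysM (Lyz2) locus, which is active in myeloid cells (LysM+/cre). The 3 samples without cre (LysM+/+) were the controls. The table held 41345 probe sets, from which 22180 genes were tested. The medians of the 7 arrays lay between 5.16 and 5.21 on the log2 scale. Array profiles correlated across all probe sets at 0.972 to 0.982 within genotypes and at 0.968 to 0.977 between genotypes. The number of arrays limits the precision of every value.

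The signal of Rictor, the floxed gene, did not separate the genotypes. It averaged 7.76 ± 0.030 (SD, n = 3) on the LysM+/+ arrays and 7.88 ± 0.25 (SD, n = 4) on the LysM+/cre arrays, a log2 difference of 0.12 ± 0.13 (SE, adjusted p = 0.749). The individual values were 7.76, 7.74 and 7.80 without cre, and 7.72, 7.76, 8.25 and 7.80 with cre. Without LysM+/cre array 3 the difference was -0.0040. Lyz2, a lysozyme gene and the site of the cre insertion, averaged 10.20 ± 0.14 without cre and 10.08 ± 0.22 with cre, a difference of -0.13 ± 0.13 (SE, adjusted p = 0.722) that ranged from -0.18 to -0.027 when 1 array was left out, the latter without LysM+/cre array 3. The part of each gene that its probe set covers is not given in the sources used here, so neither value checks the labels, and the genotypes are those of the arrays as labelled.

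The comparison of genotypes asks how loss of mTORC2 alters colon macrophages during colitis. No group carried cre without floxed Rictor alleles. Effects of Rictor loss, of cre itself and of its insertion into Lyz2 therefore cannot be told apart. By camera with a preset inter-gene correlation, immediate early and heat shock genes were lower on the LysM+/cre arrays and oxidative phosphorylation and glycolysis genes higher. With an estimated correlation these calls were lost (adjusted p = 0.628, 0.628 and 0.634), and without LysM+/+ array 2 the glycolysis call was lost too (adjusted p = 0.0769). Egr1, an immediate early transcription factor, was 1.30 lower on the log2 scale (SE 0.19), with 10.03 ± 0.27 (SD, n = 3) against 8.74 ± 0.30 (SD, n = 4). Gadd45g, a growth arrest and DNA damage inducible gene, was 1.16 lower (SE 0.14). The paired receptor genes Sirpb1a and Sirpb1c were higher by 1.22 (SE 0.17) and 1.55 (SE 0.26). Each of these 4 genes had no overlap between the arrays of the genotypes, and none passed the adjustment over all genes. They were picked among the genes of smallest unadjusted p, so the lack of overlap is no separate support.

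No gene passed an adjusted p of 0.05 in limma, where the smallest was 0.195, and the count was also 0 at an adjusted p of 0.1. At an unadjusted p under 0.05 there were 2549 genes against 1109 expected with no effect, of which 1456 were higher and 1093 lower with cre. Of these, 501 differed at least 1.5-fold, with 178 higher and 323 lower. That balance was 225 higher and 294 lower with array medians set equal, 269 and 308 without LysM+/cre array 3, and 217 and 190 with the fibroblast score as a covariate. Without LysM+/+ array 1 the count was 808. The arrays of the genotypes did not overlap for 1950 genes, or 8.79%, where chance gives 5.71%. A per-gene variance without moderation called 2 genes, Arhgef40 and Gmnn, named here after their values were seen.

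None of the genes named next passed the test, and they are given as values. Among genes at least 1.5-fold higher with cre whose higher group lay above the median gene, the smallest unadjusted p-values belonged, in that order, to Nipsnap3b (0.60), Grpel2 (0.60), a mitochondrial protein import factor, Sirpb1a, B3gnt8 (0.71), Aasdhppt (0.71) and Tfip11 (0.86). Next came Tnfrsf14 (0.77), the receptor for LIGHT and BTLA, with Rcn1 (0.68), Ccng1 (0.79), a p53 target, Med4 (0.80), Sirpb1c and Itga9 (0.62), an integrin subunit. Sirpb1a and Sirpb1c are close paralogs whose probes may share targets, so their values are not independent. On the lower side the order was Gadd45g, Scai (-1.05), the nuclear RNA Neat1 (-0.62), Egr1, Adam33 (-0.96), Pyroxd2 (-0.60) and Itih5 (-1.43). The rest were Zfp398 (-0.60), Adgrl1 (-0.75), Calcrl (-0.91), which encodes a receptor for adrenomedullin and CGRP, Sbno2 (-0.62), and the circadian repressor Nr1d1 (-1.01).

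**Figure D1:**
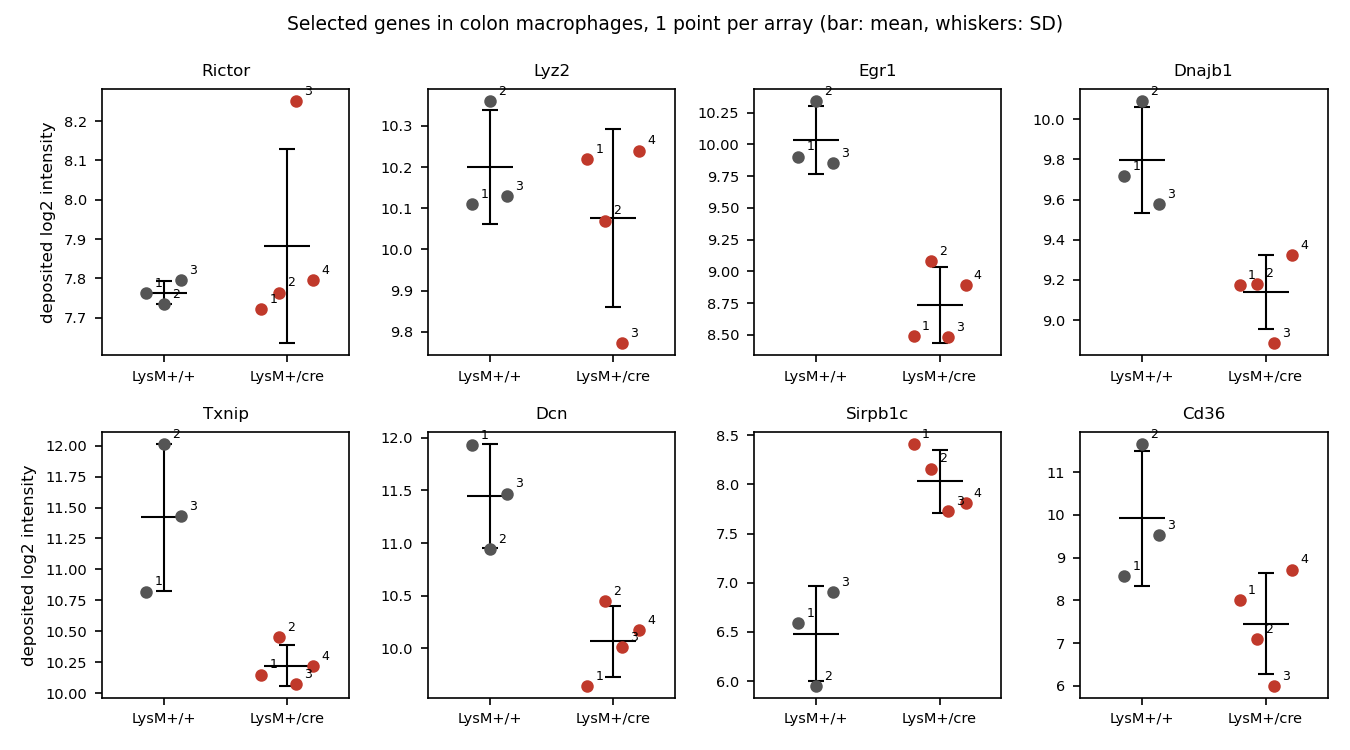
Deposited log2 intensity (vertical axis) of 8 genes on the 3 LysM+/+ and 4 LysM+/cre arrays, with 1 numbered point per array, a bar at each group's mean and whiskers of 1 SD. Rictor and Lyz2 overlap between genotypes, Egr1, Dnajb1, Txnip, Dcn and Sirpb1c do not, and Cd36 varies widely within both.

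Of 28 gene lists fixed in advance, 10 shifted with the genotype by camera with a preset inter-gene correlation of 0.01, 5 up and 5 down. With the correlation estimated for each list none of the 10 held, and the smallest adjusted p was 0.628. Calls gained by leaving out an array or by another setting, given further on, are also calls with the preset correlation, and with an estimated one no list was called under any of 18 other settings (smallest adjusted p = 0.203). The immediate early and heat shock list had the smallest p with the preset correlation, with a mean log2 difference of -0.42 and 21 of its 23 genes lower (adjusted p = 2.4e-07, and adjusted p = 0.628 with an estimated correlation). Adjusted over the list alone, 7 members were lower and 1 higher, against 0 over all genes tested. Egr1 (adjusted p = 0.00686 over the list alone) led it, followed by the chaperone genes Dnajb1 (-0.65 ± 0.15 SE) and Hsp90aa1 (-0.52 ± 0.14 SE). Ier3, an NF-kB target that limits apoptosis, went the other way (0.70 ± 0.18 SE). The fibroblast score, given further on, was also lower with cre as a group mean, but the genotypes overlapped. It was 0.19 on LysM+/cre array 2 against 0.061 on LysM+/+ array 2.

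FoxO-induced genes fell by a mean of 0.24, with 13 of 18 lower (adjusted p = 0.0214, and adjusted p = 0.628 with an estimated correlation). The estimated correlation of this list was -0.025, and camera with it gave an unadjusted p of 0.034. Txnip, an inhibitor of thioredoxin and of glucose uptake, was 1.20 lower (SE 0.26), the insulin receptor gene Insr 0.49 lower (SE 0.11) and the pseudokinase gene Trib1 0.41 lower (SE 0.094). These 3 passed when adjusted over the list alone, each at an adjusted p of 0.0213, against 0 over all genes tested. Without LysM+/+ array 3 the list lost its call, with a mean of -0.24. The 9 mTORC2 component genes did not shift as a list in one direction (mean 0.01, adjusted p = 0.665), but fry's mixed test, which asks for change in either direction, called them (adjusted p = 0.0381). Of these genes Deptor, an inhibitor of mTOR kinase, was lower by 0.42 ± 0.093 (SE, adjusted p = 0.0249 over the list alone). AKT, SGK and PKC kinase genes had a mean difference of 0.09 (adjusted p = 0.286), with no member past the adjustment over the list alone. Its smallest p-values belonged to Sgk1 (0.55), Akt2 (0.17) and Akt1 (0.16). Sgk1 lay at 8.84 on LysM+/+ array 2 against 9.99 and 9.80 on LysM+/+ arrays 1 and 3, so its difference rests largely on that array. The mean of the kinase list ranged from 0.059 to 0.11 when 1 array was left out.

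Genes of energy metabolism and growth were higher with cre. All 24 oxidative phosphorylation genes were higher, by a mean of 0.19 (adjusted p = 7.1e-07, and adjusted p = 0.628 with an estimated correlation), with 0 past the adjustment over the list alone. They included Ndufa1 (0.37), Ndufb3 (0.22) and Atp5a1 (0.20), which encode subunits of complex I and ATP synthase. Without LysM+/+ array 3 the mean was 0.13 and the call held with the preset correlation. Of the glycolysis genes, 15 of 18 were higher, by a mean of 0.36 (adjusted p = 0.00269, and adjusted p = 0.634 with an estimated correlation), led by Pgk1 (0.87), Gapdh (0.33) and Pkm (0.52), with 0 past the adjustment over the list alone. Without LysM+/+ array 2 the mean was 0.19 and the call was lost. Ribosomal protein genes rose by a mean of 0.12, with 23 of 24 higher (adjusted p = 0.00779, and adjusted p = 0.743 with an estimated correlation), among them Rplp0 (0.65), Rpl27 (0.18) and Rpl10a (0.26). The 2 probe sets of Rpl27 differed in sign, and those of Rplp0 lay at 0.65 and 0.18. The call was lost without LysM+/+ array 3 (mean 0.07), without LysM+/cre array 2 (mean 0.08) and after quantile normalization (mean 0.09). Cell cycle genes rose by a mean of 0.18, with 24 of 29 higher (adjusted p = 0.0119, and adjusted p = 0.744 with an estimated correlation), including the replication genes Rrm2 (0.52, but 0.14 on its other probe set), Mcm2 (0.44) and Mcm5 (0.55). Without LysM+/+ array 1 the mean was 0.08 and the call was lost. In neither list did a member pass over the list alone. With the fibroblast score as a covariate, a fit chosen after the data were seen, the oxidative phosphorylation and immediate early lists held their calls with the preset correlation. The FoxO (mean -0.25, adjusted p = 0.0761) and glycolysis lists (mean 0.31, adjusted p = 0.0595) lost theirs with means close to those without the covariate, while the means of the cell cycle (0.055), epithelial (-0.13) and endothelial lists (-0.10), which also lost theirs, were smaller. With a score of all outside cell types as a covariate the FoxO list lost its call at a mean of -0.23 (adjusted p = 0.0777) and the ribosomal list at 0.082 (adjusted p = 0.119). The endothelial mean was then -0.10 and the epithelial mean reversed to 0.20, neither called.

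**Figure D2:**
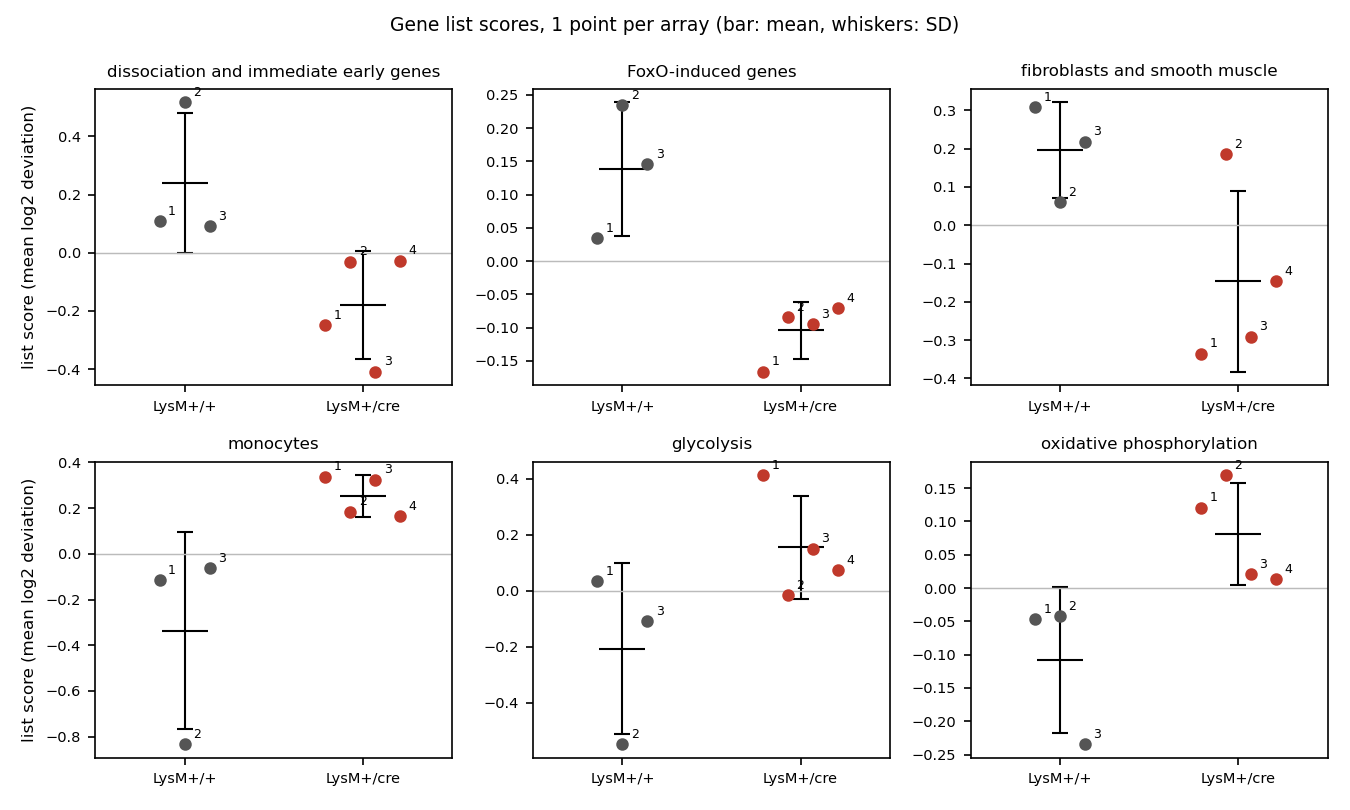
Scores of 6 gene lists on each array: the mean log2 deviation of the members from their means over all 7 arrays (vertical axis), for 3 LysM+/+ and 4 LysM+/cre arrays, with 1 numbered point per array, a bar at each mean and whiskers of 1 SD. LysM+/+ array 2 lies lowest for monocyte (-0.83) and glycolysis genes (-0.55) and highest for immediate early genes (0.52).

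Monocyte genes rose by a mean of 0.59, with 13 of 17 higher (adjusted p = 0.0214, and adjusted p = 0.628 with an estimated correlation), and without LysM+/+ array 2 the mean was 0.34 and the call was lost. The estimated correlation of this list was 0.052, and camera with it gave an unadjusted p of 0.086. The monocyte antigen gene Ly6c2 was 1.09 higher and Itgam, which encodes the gating marker CD11b, 0.53 higher, while F13a1, coagulation factor XIII, was 1.08 lower. None of these passed over the list alone. Genes of resident gut macrophages did not shift (mean -0.20, adjusted p = 0.18), though they were called without LysM+/+ array 3 (mean -0.30) and had a mean of -0.034 without LysM+/+ array 2, with Fcgr1, which encodes the gating marker CD64, at 0.97, the phosphatidylserine receptor Timd4 at -0.96 and the Notch target Hes1 at -0.73. Alternative activation genes had 14 of 20 members lower (mean -0.25, adjusted p = 0.0788, called at a mean of -0.32 without LysM+/cre array 4 but with a mean of -0.15 without LysM+/cre array 3), with Tgm2 at 1.04, Irf4 at -0.91 and the haemoglobin scavenger receptor Cd163 at -0.90. For inflammatory cytokines the mean was -0.01 (adjusted p = 0.399), and the chemokine genes Ccl2 (-0.999) and Cxcl10 (-0.86) and the cytokine gene Il6 (-0.90) had its smallest p-values. Interferon response genes had a mean of -0.01 and a median of 0.07 (camera direction down, adjusted p = 0.937). This list also held Cxcl10 (-0.86), its member of smallest p, with Zbp1 at 0.93 and Irf7 at 0.84. MHC class II presentation genes (mean -0.04, adjusted p = 0.991) held the lysosomal thiol reductase Ifi30 at 0.30, Ctss at 0.26 and Cd40 at -0.25. Without LysM+/+ array 2 the inflammatory list (mean -0.34, adjusted p = 0.00237, and adjusted p = 0.597 with an estimated correlation) and the interferon list (mean -0.29, adjusted p = 0.00699, and adjusted p = 0.636 with an estimated correlation) were called as lower. No member of these 6 lists passed over the list alone.

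In the matrix remodelling and angiogenic list, Hbegf, a ligand of the EGF receptor, was lower by 0.84 ± 0.16 (SE, adjusted p = 0.0361 over the list alone), and the list did not shift in one direction (mean 0.09, adjusted p = 0.437), although fry's mixed test called it (adjusted p = 0.0381). Spp1 was not analysed here. Lysosome and phagocytosis genes had a mean of -0.04 (adjusted p = 0.52), with Cd68 at -0.20 and Atp6v1h at -0.23. Sterol and fatty acid synthesis genes had a mean of 0.09 (adjusted p = 0.328), with Elovl6 at 0.47, Srebf1 at 0.39 and Fdps at 0.61, and were called as higher without LysM+/+ array 2 (mean 0.24) and without LysM+/cre array 3 (mean 0.17). For cholesterol efflux and lipid handling the mean was -0.08, the median 0.02 and the camera direction down (adjusted p = 0.997). That list held the fatty acid translocase Cd36 at -2.46 ± 0.88 (SE), the oxysterol receptor Nr1h3 at 0.52 and the cholesterol carrier Npc2 at 0.23. The unfolded protein and integrated stress response list had a mean of 0.11 (adjusted p = 0.328, and adjusted p = 0.0416 in fry's mixed test), with the endoplasmic reticulum genes Calr at 0.42, Sdf2l1 at 0.60 and Pdia6 at 0.46. None of these 4 lists had a member past the adjustment over the list alone.

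Markers of cell types outside the gate differed between arrays. The fibroblast and smooth muscle list fell by a mean of 0.34, with 15 of 20 genes lower (adjusted p = 0.000544, and adjusted p = 0.628 with an estimated correlation). Dcn, the matrix proteoglycan decorin, was lower by 1.38 ± 0.27 (SE, adjusted p = 0.0295 over the list alone), at 11.44 ± 0.49 (SD, n = 3) against 10.07 ± 0.34 (SD, n = 4). Endothelial genes fell by a mean of 0.26, with 14 of 15 lower (adjusted p = 0.0156, and adjusted p = 0.628 with an estimated correlation), including Tek (-0.47), Lyve1 (-1.73) and Robo4 (-0.30). Lyve1 was far brighter, with a LysM+/+ mean of 9.73 against 4.66 for Tek and 5.60 for Robo4. Whether its signal came from endothelium or from the macrophages themselves was not tested. Without LysM+/+ array 3 the mean was -0.14 and the call was lost. Epithelial genes fell by a mean of 0.34, with 22 of 24 lower (adjusted p = 0.0156, and adjusted p = 0.744 with an estimated correlation), including Car4 (-0.94), Slc26a3 (-1.07) and Tff3 (-0.41). Without LysM+/+ array 3, which had the highest epithelial score at 0.94, their mean was 0.04, and without LysM+/+ array 1 it was -0.76. The call was also lost without LysM+/+ array 2 (mean -0.29) and without LysM+/cre array 4 (mean -0.19).

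The other 6 lists of outside cell types were not called with all arrays as deposited, and 3 of them were called under other settings or without single arrays. Neutrophil genes had a mean of 0.52 (adjusted p = 0.0826), with Mmp9 at 1.35, Il1r2 at 0.65 and Mmp8 at 1.79, and their score ran from -1.10 on LysM+/+ array 2 to 1.46 on LysM+/cre array 3. Their mean was 0.11 without LysM+/+ array 2 and 0.10 without LysM+/cre array 3, and they were called without LysM+/+ array 1 (mean 0.87), LysM+/cre array 1 (0.73) or LysM+/cre array 4 (0.71). Dendritic cell genes had a mean of -0.26 (adjusted p = 0.0761), with Zbtb46 at -0.38 and Flt3 at -0.74. They were called with array medians set equal (adjusted p = 0.0314) and without LysM+/+ array 1 (mean -0.44), LysM+/cre array 1 (-0.43) or LysM+/cre array 4 (-0.40), and their mean was -0.046 without LysM+/cre array 3. Eosinophil and mast cell genes had a mean of -0.09 (adjusted p = 0.997), with Tpsb2 at 0.30, Kit at -0.88 and Il5ra at 0.26. T and NK cell genes had a mean of -0.13 (adjusted p = 0.533), with Cd3d at 0.21, Klrb1c at -0.23 and Cd2 at -0.28. B and plasma cell genes had a mean of -0.06, a median of 0.02 and a camera direction of up (adjusted p = 0.863), with Cd79b at 0.39, Jchain at -0.89 and Pax5 at 0.26. Erythroid and platelet genes had a mean of -0.50 (adjusted p = 0.0761), with Itga2b at -0.17, Car2 at -1.14 and Ppbp at -1.20. They were called with array medians set equal (adjusted p = 0.0436), with dim probe sets left out (adjusted p = 0.0369), and without LysM+/+ array 1 (mean -0.73) or LysM+/cre array 3 (mean -0.61). When each outside cell type was reduced to 1 score per array, 0 of 9 scores reached p under 0.05 in an exact two-sided permutation test over all 35 splits, where 0.0286 is the smallest p possible. The fibroblast score had an exact permutation p of 0.0857 (adjusted over the 9 scores, 0.386), as had the endothelial score, the epithelial score one of 0.457 and the neutrophil score one of 0.514.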

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

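The tests of splits of the arrays were set before their results were seen, and all the other tests of explanations in this part were chosen after them. That a 95% interval across arrays must exclude 0 before 1 array is set aside as the source was asked once the results were known.

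In each of 169 values (named genes, list scores and array medians) the 4 LysM+/cre arrays were searched for 1 array far from the other 3, and 7 such values were found, where chance gives about 1 in 20. On LysM+/cre array 3, Rictor stood at 8.25 against 7.72 to 7.80 on the others, and Sgk1, an mTORC2 substrate kinase gene, at 10.34 against 10.00 to 10.01. On LysM+/cre array 1, Il1r2 stood at 12.40 against 11.61 to 11.71, and Cd3d at 5.30 against 5.17 on each of the others. On LysM+/cre array 2, Slc26a3 stood at 7.05 against 5.55 to 5.80, Rpl10a at 9.002 against 8.65 to 8.70, and Inhba at 5.69 against 7.38 to 7.57.

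Splits of the same 7 arrays into 3 and 4 bear on whether the counts exceed chance. The 501 genes past 1.5-fold were matched by 1 of 35 splits, the real one, and the highest other count was 366. That is the smallest share that 35 splits can give, so chance is made less likely for that count but is not excluded. The splits also cannot tell genotype from handling or anything else that went with it. The 10 lists called with a preset correlation were matched by 5 of 35 splits, with 11 in the highest other, so chance is not excluded for the number of lists. All 35 splits gave 0 genes past the adjusted threshold, as many as the real one.

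Immediate early and heat shock genes were lower on the LysM+/cre arrays, with the highest score on LysM+/+ array 2. Without that array the list's mean was -0.28, the other LysM+/+ scores (lowest 0.092) lay above every LysM+/cre score (highest -0.028), and the call held with a preset correlation (adjusted p = 0.000162; with an estimated one there was no call with or without that array, adjusted p = 0.597 without it), but the 95% interval of the score, -0.66 to 0.11, includes 0, so that array alone is not excluded with this few arrays. With the fibroblast score as a covariate the score differed by -0.35 against -0.42 without it and the call likewise held only with a preset correlation (adjusted p = 0.000847, and adjusted p = 0.852 with an estimated one), but the 95% interval, from -1.04 to 0.34, includes 0, so RNA from stromal cells stays open. The 6 heat shock members were lower by a mean of 0.50 (-0.50, 95% interval -0.98 to -0.024, exact permutation p = 0.0571), as handling stress before lysis could give. They belong to the list already seen to be lower, so their fall is no separate evidence. The labels give no sorting order or time, so handling and genotype cannot be told apart, and an effect of Rictor loss on these genes also stays open, untested.

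Fibroblast genes were also lower with cre as a list mean. Leaving out each array in turn left the list called with a preset correlation, at means of -0.45 to -0.28 against -0.34 with all arrays, so no single array ended the pattern, but the interval across arrays included 0 except without LysM+/cre array 2 (-0.72 to 0.16 for the smallest mean), so 1 array as the source is not excluded with this few arrays. Col1a1, Col1a2, Col3a1 and Sparc differed by 0.09 (95% interval -0.37 to 0.55) while the other 16 members differed by -0.45 (-0.83 to -0.073), and given the score of those 16 the 4 were higher by 0.61 (0.30 to 0.92). The 4 were set apart after their values were seen, and the makeup of any stromal RNA was not measured, so this split excludes nothing. Less carry-over of fibroblasts or another mixture of stromal cells, despite the CD45 gate that would remove them, and a change of Dcn and like genes within macrophages stay open, as does genotype.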

How the results depend on the processing

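Leaving out LysM+/+ array 2 with LysM+/cre array 3, the fibroblast score as a covariate, and estimated correlations under other settings were chosen after the data were seen. Of 138 named genes besides Rictor and Lyz2, none passed the adjusted threshold under any setting run, and 1 reversed, Ppbp, at 0.087 with the other-cell-type score as a covariate. No gene passed under the alternatives except with per-gene variances, which called 2 genes (Arhgef40 and Gmnn), whose SDs among LysM+/cre arrays were 0.0022 and 0.0085. Genes past 1.5-fold numbered 1178 with every probe set as a feature (more features tested) and 337 (without LysM+/cre array 1) to 808 (without LysM+/+ array 1) when 1 array was left out. Lists called numbered 10, against 0 with estimated correlations, 0 with directional fry, 5 with mixed fry (mTORC2, matrix and unfolded protein lists among them), 5 with the fibroblast covariate, 13 with array medians set equal, 12 with dim list members left out, and 7 to 12 when 1 array was left out. The fibroblast list has no value under its own score. Rictor ranged from -0.0040 (without LysM+/cre array 3) to 0.17 (without LysM+/cre array 1) and was -0.018 without both doubted arrays, where Lyz2 was 0.053. The cause was not tested for any of these except where stated. Of the outside cell type scores, only the fibroblast score was run without each array in turn (exact permutation p of 0.1 to 0.2). The 0.1 came without LysM+/cre array 2, where the groups did not overlap, so no smaller p was possible there. The other scores were not run this way, and 2 arrays against 4 allow no exact p under 0.067. No alternatives were run for Spp1. The deposited values carry no background signal, so detection was not assessed.

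Some list means reversed under other settings, and of those lists epithelium alone was called. Most were near 0, but not those of neutrophil (0.52), epithelial (-0.34), dendritic (-0.26) and resident macrophage genes (-0.20). With quantile normalization mTORC2 genes were at -0.0067, and with medians set equal inflammatory genes at 0.011 and interferon genes at 0.018. Interferon genes were at 0.0064 with dim genes or dim members left out and at 0.0045 with array weights, where MHC class II genes were at 0.0079. With the other-cell-type score as a covariate, which the outside cell type lists partly make up, mTORC2 genes were at -0.017, inflammatory at 0.18, eosinophil and mast cell at 0.043, epithelial at 0.20, interferon at 0.11 and sterol genes at -0.065. With the fibroblast covariate mTORC2 genes were at -0.033, inflammatory at 0.28 and interferon genes at 0.064. Without both doubted arrays resident macrophage genes were at 0.082, neutrophil at -0.30, dendritic at 0.045, MHC class II at 0.18 and matrix genes at -0.0052, the inflammatory (-0.40, adjusted p = 0.000189) and sterol lists (0.32, adjusted p = 0.00143) gained calls, and the monocyte (0.32), glycolysis (0.19) and epithelial lists (-0.28) lost theirs. Leaving out 1 array gave ranges of -0.011 to 0.045 for mTORC2, -0.34 to 0.18 for inflammatory, -0.15 to 0.048 for eosinophil and mast cell, -0.14 to 0.024 for B and plasma cell, -0.76 to 0.037 for epithelial, -0.29 to 0.24 for interferon, -0.15 to 0.14 for MHC class II, -0.093 to 0.24 for sterol, 0.10 to 0.87 for neutrophil, -0.44 to -0.046 for dendritic, -0.30 to -0.034 for resident macrophage, -0.34 to -0.15 for alternative activation, -0.22 to -0.035 for T and NK cell, 0.0017 to 0.19 for matrix, -0.13 to -0.036 for cholesterol, -0.073 to -0.014 for lysosome and -0.73 to -0.34 for erythroid and platelet genes. Other reversed means within these ranges were -0.0036 for mTORC2 and 0.031 for interferon genes without LysM+/+ array 1, -0.0046 for mTORC2, 0.13 for inflammatory and 0.012 for MHC class II genes without LysM+/+ array 3, 0.074 for inflammatory genes without LysM+/cre array 1, and for interferon genes 0.039 without LysM+/cre array 2 and 0.10 without LysM+/cre array 3. No list was called with an estimated correlation under any of these settings. Gained calls with the other-cell-type covariate were those of alternative activation (-0.40), resident macrophage (-0.34), neutrophil (0.86) and dendritic genes (-0.42), and with the fibroblast covariate of dendritic genes (-0.52). The cause was not tested.

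Same-numbered arrays correlated in their deviations at -0.11, 0.12 and 0.10, so the values do not show that the numbers pair the samples, and whether they do is not given in the sources used here. Only LysM+/+ array 3 correlated best with the LysM+/cre array of its own number. With the replicate number as a block, 0 genes passed, 488 passed 1.5-fold and 14 lists were called with the preset correlation. The epithelial list then lost its call. Alternative activation, resident macrophage, neutrophil, dendritic, and erythroid and platelet genes gained calls. With an estimated correlation no list was called under the block (smallest adjusted p = 0.44).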

Other observations

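The receptor list was fixed and its test set before its values were seen; the other tests in this part were chosen after the values they bear on. For the test without LysM+/+ array 2 and the monocyte test, a 95% interval that excludes 0 was asked only once their results were known; before that, groups without overlap were enough.

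Beyond the genes chosen by the rule set in advance, the largest differences past 1.5-fold at an unadjusted p under 0.05 were read after the data were seen, and none passed the adjusted threshold. Higher with cre stood Ly6i (1.87), Inhba (1.85), which encodes the activin A subunit, Egln3 (1.57), an oxygen-sensing prolyl hydroxylase, Cfb (1.35), complement factor B, Spon1 (1.33), Rrp1b (1.26) and Lst1 (1.25). Lower stood Mptx1 (-3.01), a pentraxin, Sycn (-2.30), Fmo2 (-1.78), Cbr2 (-1.75), Klk1 (-1.71), Vsig4 (-1.70), a complement receptor of tissue macrophages, and Scn7a (-1.70). Fgfr1 and Tns1 (both -1.65), Pla2g10os (-1.57), Igfbp3 (-1.55), Dnm1 (-1.54) and Zbtb16 (-1.54) followed. The 2 probe sets of Svep1 disagreed, at -1.59 and 0.07. SEs were wide for several, such as 1.25 for Mptx1. On LysM+/+ array 2 Mptx1 stood at 10.57 against 4.90 and 6.94 on LysM+/+ arrays 1 and 3, and Vsig4 at 7.50 against 5.15 and 5.36. The differences of Mptx1 and Vsig4 thus rest largely on that array. Others leaned on it in part, such as Sycn (10.44 against 8.17 and 6.75) and Cbr2 (11.87 against 10.18 and 9.35). Egln3 was lowest there (4.97 against 6.68 and 5.985). Ly6i stood at 7.54 on LysM+/cre array 1 against 4.82 to 5.89 on the other LysM+/cre arrays.

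A group of myeloid receptors stood out among the higher genes, most of them activating, with Pilra the inhibitory partner of the Pilrb genes. Sirpb1a (1.22), Sirpb1c (1.55), Pilra (1.18), Pilrb1 (1.30), Trem1 (1.47), Trem3 (1.76) and Treml4 (1.31) averaged 1.40 higher, and were picked for the size of their differences. A second list of myeloid receptors and adaptors, activating and inhibitory, which shares no gene with these or the fixed lists, was higher by a mean of 0.35 in 18 of 22 genes (camera adjusted p = 5.07e-05 with a preset correlation and adjusted together with the fixed lists, adjusted p = 0.515 with an estimated one, exact permutation p = 0.0286), which is what a shift of such receptors as a group may give. Its members included Fcgr4 (1.14), Clec4a3 (0.83), Pilrb2 (0.79), the inhibitory Siglece (0.70), Clec5a (0.53), Clec4n (0.39), the adaptor Tyrobp (0.31), Fcer1g (0.27), Clec4a1 (0.25) and Fcgr3 (0.23), with Lilrb4a, also inhibitory, at -0.21. By name this second list holds relatives of the 7 (Pilrb2, Treml1 and Treml2), so it is not fully independent of them. Without LysM+/+ array 2 it still differed by 0.26 (95% interval of its score 0.069 to 0.45). Its exact permutation p was then 0.0667, the smallest possible. It kept its call by camera with a preset correlation (adjusted p = 0.000663), and an estimated one was not run without that array. This argues only weakly against that array alone, since the limits were set after the list's mean was known. With the neutrophil score as a covariate the second list's score differed by 0.32 (95% interval 0.040 to 0.60), which likewise argues only weakly against neutrophil carry-over as the whole account. The gate on CD64 and MHC class II would also remove most neutrophils, and genotype stays open, untested. Both tests were first run on the 7 receptors, the neutrophil one set before its result was seen, and gave 1.09 without LysM+/+ array 2 and 1.30 (95% interval 0.26 to 2.34) with the neutrophil score. They were moved to the second list, with limits set anew, after those results and the mean of the second list were known, because genes picked for their size cannot test whether the difference holds.

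FoxO factors are held back by AKT, which mTORC2 phosphorylates, so loss of mTORC2 might be thought to raise FoxO-induced genes. The list's score was lower with cre, by 0.24 on the log2 scale (-0.24, 95% interval -0.38 to -0.10). All 4 LysM+/cre arrays lay below all 3 LysM+/+ arrays (exact permutation p = 0.0286, the smallest possible). These transcripts were thus not raised as a list. By camera with an estimated correlation the list was not called (adjusted p = 0.628). The rule for this comparison was written after the pattern was seen and could not come out otherwise. FoxO activity was not measured and the Rictor signal did not separate the genotypes, so nothing is concluded about FoxO output after loss of mTORC2.

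Egln3, high with cre, and the glycolysis genes are HIF targets, so HIF activity may differ. A list of other HIF targets had a mean of 0.18 (95% interval -0.040 to 0.40), with 10 of 13 higher (camera adjusted p = 0.0437 with a preset correlation, adjusted p = 0.52 with an estimated one) and Egln1 at 0.65 and Mxi1 at 0.40. As first written, a mean under 0.2 was to count against HIF activity. The interval, used in its place once the mean was known because 0.18 lies below 0.2 by less than its spread, includes both 0 and 0.2 and leaves this hypothesis undecided. Without LysM+/+ array 2 the mean was 0.13.

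A less mature population inside the gate is another hypothesis, although the sort took cells without Ly6C, which would remove monocytes and the earliest macrophage stages. The monocyte score minus the resident macrophage score was higher with cre by 0.79 (95% interval -0.22 to 1.79), with no overlap of the groups (exact permutation p = 0.0286, lowest LysM+/cre array 0.055 and highest LysM+/+ array 0.032). Without LysM+/+ array 2 the difference was 0.38 (exact permutation p = 0.133, with 0.0667 the smallest possible). The interval includes 0, the difference rests largely on 1 array and F13a1 went the other way, so this hypothesis stays undecided.

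Of the 100 measured genes nearest Lyz2 (50 on each side in GRCm38.p6), 1 passed 1.5-fold at an unadjusted p under 0.05, against 2.26 expected.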
